A study of Mus musculus with 2 samples.

How the data were processed

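Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map H3K27me3, the trimethylated lysine 27 of histone H3 that Polycomb complexes deposit at silent genes, in limb tissue of mouse embryos at day 14.5. Per the labels, 2 biological replicates were collected, from separate pools of 24 and 34 embryos of both sexes. All samples belong to 1 group, so no comparison between conditions was possible. Each value of a replicate therefore comes from 1 pool of embryos.

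Reads were processed by the authors before deposit, and only lists of peaks were analysed here. Per the file headers and accompanying notes, coordinates are on mm10 (GRCm38), peaks were called once on each replicate and once on both replicates pooled, and a list of replicated peaks was derived from the pooled and per-replicate lists. Replicate 2 combined 2 technical replicates. Replicate 1 was set against 1 control file, and replicate 2 and the pooled list against 2 each. The aligner, the peak caller and its thresholds were not given in the sources used here. The deposited −log10 p starts at 2.03 in the replicated list, 2.00 in the pooled list, 2.05 in replicate 1 and 2.04 in replicate 2. Control reads and signal tracks were not analysed here. Read counts were not among the files used, so the sequencing depth is unknown, and no interval that needs it is given.

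For every peak the authors gave a fold enrichment over control (a ratio), −log10 of the p-value, −log10 of the q-value adjusted within the list, a display score and a summit offset. These are the authors' own values of each peak, and they were used only to describe, rank or filter peaks within a list. The deposited score column and the summit offset entered no result. In the replicated list the authors' fold equals that of the pooled list, since its peaks are a subset of the pooled peaks.

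Gene positions came from GENCODE release M21 (basic set, GRCm38), and sequence from GRCm38.p6. Chromosomes 1 to 19, X and Y were used. Of the protein-coding genes, 54 were left out because they shared a symbol, which left 21884. A gene was called marked when replicated peaks covered at least 1 bp within 2 kb of any of its transcript starts. Its coverage was the percent of the 10 kb around a start (5 kb on each side, the start with the highest percent) that peaks covered. For named genes this percent is given for the replicated list, with the mean ± SD of the separate replicate lists (n = 2) beside it. The replicate lists hold narrower and more numerous peaks, so their mean lies below the replicated value for most marked genes.

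Overlaps between lists needed 1 bp. They were set beside 100 circular shifts of the peaks along each chromosome, started beyond 3 Mb because most chromosomes open with unsequenced bases. Correlations of fold between replicates were computed across peaks, which are not independent replicates, so no p is given. In all, 29 gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The lists were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives given under the processing of the results. Several lists share genes, so their tests are not independent of each other. Limb patterning genes were compared with 6 other lists by two-sided Fisher's exact tests and by permutation of the gene labels (100000 resamples), each adjusted over the 6 pairs. Hox genes of paralog groups 9 to 13 were compared with groups 1 to 8 by two-sided permutation within the 4 clusters, exact within a cluster and resampled over all clusters, adjusted over 5 tests. Neighbouring genes are not independent, so these p-values describe the lists and not a population of animals. Intervals of percentages of genes are 95% Wilson intervals, and they treat genes as independent.

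Alternatives were the pooled list, each replicate alone (peaks with −log10 q of at least 2, but the whole replicate lists for the X chromosome), stricter thresholds (−log10 q of at least 2, −log10 p of at least 5), other overlaps (50% of either or of both peaks, peaks within 1 kb merged), windows of 1 kb and 5 kb, the 5′ end of each gene only, a minimum of 500 bp, a background matched on CpG content (observed over expected CpG around the start, 10 classes, 10000 draws), and a rotation of the calls along the gene order. For the list pairs no genes were matched. Gene labels were permuted within the CpG classes instead, and the difference beyond the mean of these permutations is given.

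Named genes followed a fixed rule. It took the 20 genes with the highest coverage (at most 2 per 100 kb), up to 4 most covered and up to 4 unmarked members (alphabetical) of each list, all Hox genes, Actb and Gapdh, the 10 windows of 100 kb with the most peak sequence, and the 5 peaks of highest fold found in 1 replicate only. Other genes named in the text were chosen after their values were seen, as were single peaks picked for their p-value, fold or width.

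Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1. The code was tested on simulated data. Covered bases matched bedtools in 4000 of 4000 windows. For the location of peaks, the replicated peaks shifted along each chromosome (16739 intervals) gave 0.973-fold at gene starts, and placing 30% of them on starts gave 7.15-fold. The first value was set against shifts of the same kind, so it tests the code and not the choice of shifts. For the gene lists (21884 genes), 98.1% of changed lists of 20 genes and 1.05% of unchanged lists were called. For the 39 Hox genes, 6% of unchanged sets and 100% of lowered sets passed 0.05, and for the list pairs (92 genes) 4% of equal pairs did. In the simulations of lists, Hox genes and pairs each gene was drawn independently. Their rates therefore do not cover neighbouring genes that share a peak.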

Results

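H3K27me3 was profiled by ChIP-seq in embryonic mouse limbs at day 14.5, a stage at which digits, cartilage, muscle and nerves are forming. The data comprised peak lists from 2 biological replicates, each a pool of embryos, together with a list called on both replicates pooled and a list of replicated peaks. The replicated list held 16738 peaks covering 18.8 Mb, or 0.689% of the genome, with a median width of 655 bp and a median fold enrichment over control of 3.74. The pooled list held 63282 peaks (31.3 Mb, median width 272 bp, median fold 2.77). Replicate 1 gave 51610 peaks (21.3 Mb, 255 bp, fold 3.27) and replicate 2 gave 43920 (18.4 Mb, 265 bp, fold 3.32). The share of peaks with a −log10 q of at least 2 was 96.7% in the replicated list, 60.2% in the pooled list, 49.4% in replicate 1 and 51.3% in replicate 2. No list held a peak on the Y chromosome. Sequencing depth was unknown, so differences in peak number between the lists could not be set against it.

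The widest marks lay mainly on genes of developmental transcription factors, and the highest fold values on genes of varied function. The highest fold values of the replicated list fell on exons of Nrxn2 (a presynaptic adhesion protein, fold 12.7), Pnma2 (11.3), Pou3f3 (a neural POU factor, 10.9), Kcnk12 (a potassium channel, 10.9) and Dio3 (the deiodinase that inactivates thyroid hormone, 10.8). The widest peak, 20366 bp at chromosome 7:79496555-79516920 (GRCm38), spanned exons of the Mir9-3 host gene, whose product miR-9 acts in neural progenitors. It was followed by peaks over Gsx2 (19107 bp), Gata2 (17575 bp), Hoxb4 and Hoxb5 (17263 bp), Irx4 (17206 bp) and Neurod2 (16830 bp). By 100 kb windows, the most densely marked sequence was the HoxC cluster, with 89.8 kb covered at chromosome 15:102900001-103000000 and 60.3 kb in the next window. HoxB windows held 73.5 kb and 59.5 kb, and the HoxD window held 59.7 kb. The remaining windows of the top 10 held Rhcg beside Mir9-3 (56.6 kb), Dmbx1 and Faah (48.6 kb), Zic4 and Zic1 (48.3 kb), Pax2 (46.4 kb) and Tbx3 (45.7 kb).

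Whether the replicates marked the same places was asked first. Strong peaks were found in both replicates, while most weak peaks were found in 1. Of the replicate 1 peaks, 21102 (40.9%) overlapped a replicate 2 peak, and 21922 (49.9%) of the replicate 2 peaks overlapped a replicate 1 peak. With replicate 2 shifted along the chromosomes, a mean of 1.32% of the replicate 1 peaks overlapped. The Jaccard index of covered bases was 0.351, against a mean of 0.00419 and a maximum of 0.006 in the shifts. Among peaks with −log10 q of 10 or more, 1219 of 1221 (99.8%) in replicate 1 and all 661 in replicate 2 were shared. The shares were 94.6% and 96.9% at −log10 q of 5 to 10, 49.8% and 59.3% at 2 to 5, and 21.4% and 30.3% below 2. Across the 21102 shared replicate 1 peaks, fold values of the replicates correlated with Pearson's r of 0.531 and Spearman's rho of 0.466.

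Peaks found in 1 replicate only were narrower, weaker and less often near genes' starts than shared peaks. In replicate 1 they numbered 30508 (59.1%), with a median width of 220 bp, a median fold of 3.16 and 13.5% within 2 kb of a transcript start. The shared peaks of that list had a median width of 411 bp, a median fold of 3.81 and 40.7% near a start. Replicate 2 gave 21998 such peaks (50.1%; 223 bp, fold 3.10, 13.4% near a start), against 390 bp, fold 3.66 and 40.4% for its shared peaks. The replicate 1 peaks of highest fold without a partner lay at chromosome 17:5940026-5940569 (fold 6.96), 2:13009587-13009982 in an exon of C1ql3 (6.64), 4:22152558-22152826 (6.64), 15:103067973-103068367 (6.60) and 1:5917738-5918114 (6.33), and all but the C1ql3 peak were intergenic. Those of replicate 2 lay in introns of Meis2 (chromosome 2:116019715-116020033, fold 6.20), Rbfox3 (11:118684823-118685220, 5.92), Wnt10a (1:74796226-74796829, 5.64) and Gm8909 (17:36166160-36166669, 5.64), and in intergenic sequence at 19:28834540-28835033 (5.92).

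The replicated list kept the wide and strong part of the pooled list. It comprised 26.4% of the pooled peaks but 18.8 Mb of the 31.3 Mb that the pooled list covered. The 46544 pooled peaks outside it had a median width of 238 bp, a median fold of 2.60 and a median −log10 q of 1.91, against 5.34 for the replicated peaks. All 14271 pooled peaks that overlapped a peak of each replicate by at least 50% of either peak were in the replicated list. Another 2467 replicated peaks (14.7%) did not meet that overlap, and 2350 lacked an overlap of even 1 bp with one of the replicate lists or both: 1206 met a peak of replicate 1 only, 1060 a peak of replicate 2 only and 84 neither. The rule that admitted these peaks was not given in the sources used here.

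Across the genome the mark was concentrated at gene starts. Of the replicated peak sequence, 7.41 Mb (39.4%) lay within 2 kb of a transcript start of a protein-coding gene, 9.23-fold the mean of 100 circular shifts (4.28%, highest 4.88%). The rest of gene bodies held 28.3%, below the 38.7% of the shifts, and sequence outside genes held 32.3%, below 57.0%. The 6375 peaks near starts had a median width of 900 bp and a median fold of 4.08, against 572 bp and 3.57 for the other 10363. In all, 3376 of 21884 protein-coding genes (15.4%) were marked, and 3275 of these (97.0%) also had a peak near a start in both replicate lists. That list was derived with the replicate lists, so a high share follows in part from its making. The replicate lists on their own marked 4488 and 4166 genes. Peaks covered at least 50% of the 10 kb around a start in 741 genes and at least 90% in 156.

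The 20 most covered genes were mainly developmental transcription factors of the nervous system, gut, blood and trunk. Complete coverage of the 10 kb around a start was found for Skor1 (100%; 94.7 ± 1.63% in the replicate lists, SD, n = 2), Grik3 (a kainate receptor), Neurod2 (97.1 ± 0.806%), Gata2 (94.1 ± 5.71%), Nkx6-2, Six3 (97.1 ± 0.389%), Gsx2 and Prdm13. Coverage was between 99.2% and 99.7% for Cdx2, Espn, Onecut1, Tal1, Lhx6, Hoxc12, Pax6, Pax5, Hoxb5, Hoxb6, Foxf2 and Insl3. Cdx2, which specifies the intestine, was covered at 99.6% (92.3 ± 0.332%), Tal1, required for blood formation, at 99.6% (87.7 ± 5.49%), and Pax6, required for the eye, at 99.4% (95.8 ± 1.81%). Actb and Gapdh, used by every cell, had no peak in the 10 kb around their starts in any list.

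Which classes of genes carried the mark was tested with the fixed gene lists. By Fisher's exact test 24 of the 29 lists differed from other protein-coding genes after Benjamini-Hochberg adjustment, 20 marked more often and 4 less often. Transcription factors of the neural, endoderm and heart lists were nearly all marked, though 2 of the heart factors are also on the limb patterning list. Of 60 neural transcription factors 59 had a peak at the start (98.3%, 95% CI 91.1 to 99.7; 15.2% of other genes; exact p = 4.3e-47, adjusted exact p = 6.2e-46), and the exception was Neurod6, with 5.88% of its 10 kb covered. Among endoderm transcription factors 21 of 24 were marked (exact p = 1.1e-14, adjusted p = 6.2e-14), including Cdx2, Onecut1, Foxa2 (97.9%; 92.9 ± 2.11%) and Mnx1 (97.6%; 86.6 ± 3.87%). The 3 unmarked members were Hnf1a, Hnf4a and Isx. Of 16 heart transcription factors 15 were marked (exact p = 8.9e-12, adjusted p = 3.7e-11), led by Tbx1 (98.6%; 93.3 ± 5.80%), Wt1, Tbx20 and Hand1, and Mef2c was the exception.

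**Figure D1:**
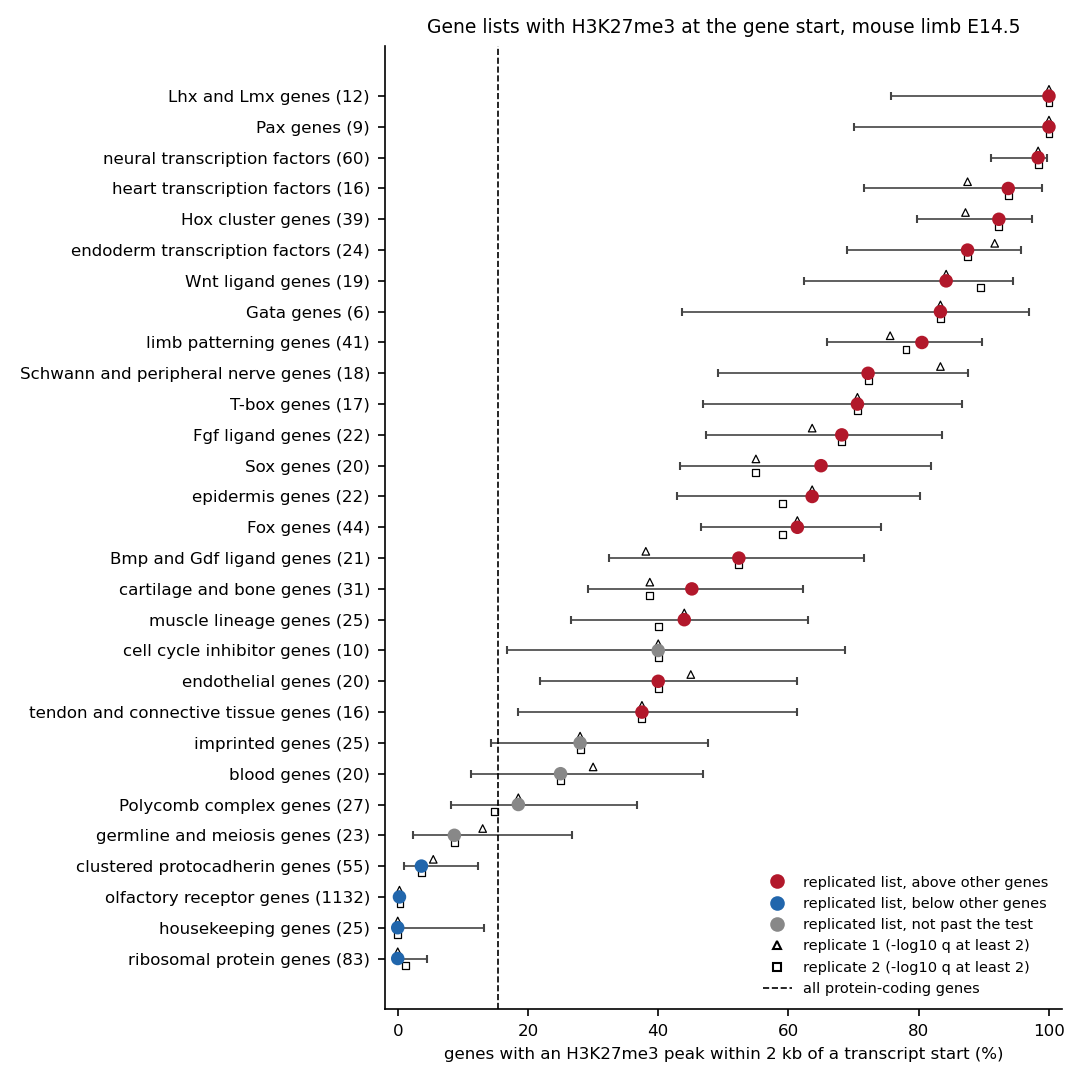
Percent of the genes of each list with an H3K27me3 peak within 2 kb of a transcript start (x axis), by list (number of genes in parentheses). Circles give the replicated list with 95% Wilson intervals, triangles and squares the replicate lists at −log10 q of at least 2, and the dashed line all protein-coding genes (15.4%).

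Genes that pattern the limb itself were also marked in large part. Of 41 limb patterning genes 33 had a peak at the start (80.5%, 95% CI 66.0 to 89.8; exact p = 3.8e-20, adjusted exact p = 2.7e-19). The most covered were Irx3 (89.9%; 71.2 ± 0.0707%), Dlx6 (89.6%; 79.1 ± 14.1%), Fgf8, the signal of the apical ectodermal ridge (87.7%; 78.8 ± 3.95%), and Pitx1, a hindlimb factor (86.2%; 60.7 ± 0.297%). Shh, the signal of the posterior limb margin, was covered at 71.6% (64.9 ± 4.20%), the hindlimb factor Tbx4 at 57.4% (43.5 ± 3.50%) and the forelimb factor Tbx5 at 49.2% (43.1 ± 17.2%). No replicated peak lay within 2 kb of the starts of 8 genes, Fgf10, Gli1, Gli3, Prrx1, Prrx2, Ptch1, Twist1 and Wnt5a, most of which act in limb mesenchyme.

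Genes of the differentiating limb tissues were split. Among cartilage and bone genes 14 of 31 were marked (45.2%, exact p = 8.20e-05, adjusted p = 1.40e-04), led by Barx1 (97.2%; 88.1 ± 8.15%), Runx3 (96.7%; 81.1 ± 6.51%), Matn4 (93.5%; 65.8 ± 2.50%) and Nkx3-2 (87.1%; 74.6 ± 4.45%). Ihh (82.1%), Runx2 (74.1%) and Acan (47.9%) were marked as well. The unmarked members included Sox9 and Sox5, the cartilage collagens Col2a1 and Col11a1, Col10a1 of hypertrophic cartilage, and the bone genes Col1a1 and Bglap. Among muscle lineage genes 11 of 25 were marked (44%, exact p = 6.28e-04, adjusted p = 9.10e-04), led by the myogenic progenitor factors Pax7 (99.0%; 86.9 ± 4.01%), Pax3 (95.9%; 86.1 ± 8.97%), Lbx1 (94.4%; 85.3 ± 0.785%) and Six1 (77.8%; 57.2 ± 17.2%). The unmarked members included Actc1, Ckm and Ttn of the contractile apparatus, the receptor gene Chrna1, Cdh15 and Myog. Tendon and connective tissue genes were marked in 6 of 16 cases (exact p = 0.0267, adjusted p = 0.0323), with the transcription factors Tcf21 (76.0%), Osr2 (62.6%), Osr1 (55.4%) and Egr1 (29.9%) ahead, and Col3a1, Dcn, Dpt and Fmod of the matrix were unmarked.

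Genes of the Schwann and peripheral nerve, epidermis and endothelial lists were marked more often than other genes. The nerve list mixes Schwann genes with neuronal genes, such as Isl1, which is also on the neural list. Of 18 Schwann and peripheral nerve genes 13 were marked (exact p = 1.1e-07, adjusted p = 2.6e-07), among them Foxd3 (95.1%), Isl1 (94.2%), Nefl (77.4%) and Egr2 (76.8%), and Cdh19, Elavl4, Mpz and Plp1 were not. Of 22 epidermis genes 14 were marked (exact p = 3.9e-07, adjusted p = 8.8e-07), with Tfap2a at 96.5%, Esrp1 at 83.3%, Cdh1 at 55.4% and Grhl2 at 46.8%, and the keratinocyte genes Flg, Ivl, Krt1 and Krt10 were not. Endothelial genes were marked in 8 of 20 cases (exact p = 0.00702, adjusted p = 0.00969), including Sox7 (95.1%), Sox17 (83.4%), Flt1 (75.1%) and Esam (69.6%), with Cdh5, Egfl7, Emcn and Eng unmarked. Blood genes did not pass the test (5 of 20, exact p = 0.220, adjusted p = 0.236), although Gata2, Tal1, Runx1 (55.9%) and Ikzf1 (50.4%) were covered. Germline and meiosis genes, of cells that the limb lacks, did not pass the test either (2 of 23, exact p = 0.564, adjusted p = 0.584), and the marked members were Meioc and Dmc1.

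Families of developmental regulators were marked more often than other genes throughout. By Fisher's exact test all 9 Pax genes (exact p = 4.9e-08, adjusted p = 1.3e-07) and all 12 Lhx and Lmx genes (exact p = 1.8e-10, adjusted p = 5.8e-10) were marked, with Pax2 at 98.8% and Lhx1 at 96.6%. Of the Gata genes 5 of 6 were marked (exact test, exact p = 4.56e-04, adjusted p = 6.96e-04), and Gata1 on the X chromosome was not. By exact tests, 27 of 44 Fox genes (p = 5.0e-12, adjusted 2.4e-11; Foxf1 99.2%), 13 of 20 Sox genes (p = 7.3e-07, adjusted 1.4e-06; Sox1 95.9%) and 12 of 17 T-box genes (p = 5.2e-07, adjusted 1.1e-06; Eomes 82.6%) were marked. Signalling ligands followed with 16 of 19 Wnt genes (exact p = 6.1e-11, adjusted 2.2e-10), 15 of 22 Fgf genes (3.7e-08, adjusted 1.1e-07) and 11 of 21 Bmp and Gdf genes (9.04e-05, adjusted 1.46e-04). Wnt10b was covered at 98.6% (90.8 ± 0.0141%), Fgf9 at 72.5% (54.2 ± 5.61%) and Gdf7 at 84.1% (76.9 ± 4.38%). Wnt5a, Wnt8a and Wnt8b were the 3 unmarked Wnt genes.

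Olfactory receptor, ribosomal protein, housekeeping and clustered protocadherin genes were marked less often than other genes, the last 2 not in every setting. Of 1132 olfactory receptor genes 3 were marked (0.265%, exact p = 4.6e-79, adjusted p = 1.3e-77), namely Olfr94 (28.3%), Olfr95 (13.7%) and Olfr222 (3.35%). That test set them against 16.3% of other genes. Of genes drawn to match their CpG content only 2.53% were marked (adjusted p from the draws = 3.62e-04), so much of the gap goes with CpG content. All 24 list calls kept their direction and stayed past 0.05 with this matching. None of 83 ribosomal protein genes (exact p = 1.8e-06, adjusted p = 3.2e-06) and none of 25 housekeeping genes (exact p = 0.0247, adjusted p = 0.0311) was marked. Among clustered protocadherin genes, which encode neuronal adhesion proteins, 2 of 55 were marked (exact p = 0.0133, adjusted p = 0.0175), Pcdhac2 (45.5%) and Pcdhac1 (16.9%). The housekeeping call was lost without replicate 1 (adjusted exact p = 0.0510) and at −log10 p of at least 5 (0.0508). It was also lost under rotation of the calls along the gene order (0.0574), with 0% marked in each of these settings. The protocadherin call was lost in the pooled list (12.7% marked, 0.0938) and under rotation (3.64% marked, 0.207). Polycomb complex genes were marked in 5 of 27 cases (exact p = 0.597, adjusted p = 0.597), led by Cbx4 (59.7%; 54.7 ± 6.75%), Phf19, Cbx8 and Cbx7. Cell cycle inhibitor genes were marked in 4 of 10 (exact p = 0.0546, adjusted p = 0.0634) and imprinted genes in 7 of 25 (exact p = 0.0937, adjusted p = 0.104). The first included Cdkn2a (88.8%; 80.5 ± 5.06%) and Cdkn2b (76.2%; 67.6 ± 1.31%), and the second Igf2 (75.6%; 55.0 ± 19.1%) and Grb10 (70.4%; 60.0 ± 0.919%). Cell cycle inhibitors passed with windows of 1 kb (adjusted exact p = 0.0480) and with a minimum of 500 bp (0.0459), and imprinted genes with the 5′ end only (32% marked, 0.0264).

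Limb patterning genes were then compared with transcription factors of other organs, with genes of cartilage, bone and muscle, and with germline genes. Limb patterning genes were less broadly covered than neural transcription factors, with a mean of 47.1 ± 32.1% of the 10 kb around the start (SD over 41 genes) against 85.5 ± 18.4% (60 genes), a difference of 38.4 percentage points. The permutation test gave p = 2.0e-05, the smallest that 100000 resamples allow (adjusted p = 6.0e-05). They were also marked less often, 33 of 41 against 59 of 60 (Fisher's exact test, p = 0.00291, adjusted p = 0.00492), a difference of −17.8 percentage points that was −9.76 in the pooled list (adjusted p = 0.0372). Endoderm factors (74.5 ± 34.1%, 24 genes) exceeded limb patterning genes by 27.4 points (permutation p = 0.00196, adjusted p = 0.00392), and heart factors (73.3 ± 32.4%, 14 genes) exceeded the 39 limb genes outside that list (47.8 ± 32.6%) by 25.5 points (permutation p = 0.0131, adjusted p = 0.0131). For both lists the share of marked genes did not pass the exact test (p = 0.733 and 0.416, adjusted p = 0.733 and 0.499). Cartilage and bone genes were covered at 24.3 ± 35.5% and muscle lineage genes at 22.9 ± 35%, below limb patterning genes (permutation p = 0.00632 and 0.00562, adjusted p = 0.00758 for each). With peaks of replicate 2 alone these gaps shrank from 22.8 to 13.5 points and from 24.2 to 15.5 points. Both calls ended when labels were permuted within classes of CpG content. Beyond the mean of those permutations, 3.74 points (adjusted permutation p = 0.596) and −1.26 points (0.846) remained, against −35.4 points for neural factors (adjusted p = 2.0e-04). Classes holding genes of only 1 list cannot be permuted and add nothing to these remainders, which are not gaps between matched genes. Germline genes were covered at 0.888 ± 3.06%, below limb patterning genes by 46.2 points (permutation p = 2.0e-05, adjusted p = 6.0e-05) and by 30.1 points with replicate 2 alone. Beyond the mean of the permutations within CpG classes, 22.5 points remained (adjusted permutation p = 2.0e-04).

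**Figure D2:**
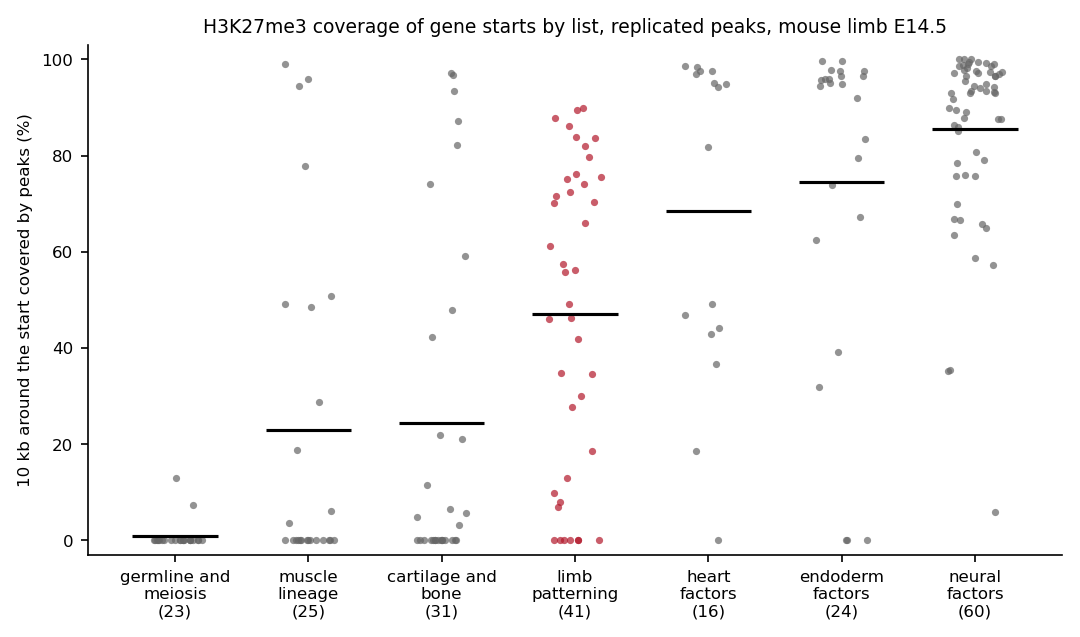
Percent of the 10 kb around the gene start covered by replicated peaks (y axis), 1 point per gene, for 7 gene lists (number of genes in parentheses); horizontal bars are means. Limb patterning genes (red) average 47.1%, and the heart list is drawn with all 16 genes, including the 2 shared with the limb list that the test left out.

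The Hox clusters, whose genes of paralog groups 9 to 13 include factors that pattern the limb along its length, were marked unevenly. HoxC was covered over 94.0% of its length (chromosome 15:102921103-103036852, GRCm38), HoxB over 73.4% (11:96194316-96368256), HoxD over 72.7% (2:74668310-74765142) and HoxA over 36.5% (6:52155590-52260880). Of 39 Hox genes 36 were marked (exact p = 2.9e-26, adjusted p = 2.8e-25), and the exceptions were Hoxa9, Hoxa10 and Hoxa11. In HoxA, genes of groups 9 to 13 were covered over 2.65 ± 5.30% of the gene and its 1 kb flanks (SD, n = 4), against 54.7 ± 25.9% (n = 7) for groups 1 to 8 (difference −52.1 points, exact permutation p = 0.00606, adjusted p = 0.0152). The difference in HoxA was −30.5 points with replicate 2 alone and −20.8 points with replicate 1 alone. Hoxa9, Hoxa10 and Hoxa11 had no replicated peak and Hoxa13 was covered at 10.6%. In HoxD the values were 44.9 ± 9.0% (n = 5) and 91.7 ± 4.95% (n = 4; difference −46.7 points, exact permutation p = 0.0159, adjusted p = 0.0265). In HoxA and in HoxD the exact p is the smallest that the number of genes allows. Coverage there was 32.1% for Hoxd13, 42.5% for Hoxd12, 43.2% for Hoxd11, 55.2% for Hoxd10 and 51.7% for Hoxd9, against 84.6% for Hoxd8.

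In HoxB and HoxC the difference did not pass 0.05. The HoxB test could not pass, since 2 genes against 8 allow too few splits for an adjusted p under 0.05 beside the other tests. Both groups of HoxB also lay near full coverage. In HoxB the means were 100% (n = 2) and 96.6 ± 3.86% (n = 8; exact permutation p = 0.267, adjusted p = 0.333), and in HoxC 94.7 ± 3.99% (n = 5) and 93.2 ± 5.12% (n = 4; exact permutation p = 0.619, adjusted p = 0.619). With replicate 2 alone and replicate 1 alone, the difference was 8.81 and 4.39 points in HoxB, and −1.11 and −10.4 points in HoxC, where its direction turned. Over all clusters, groups 9 to 13 were covered at 56.8 ± 39.9% (16 genes) and groups 1 to 8 at 82.4 ± 23.4% (23 genes; difference −25.6 points, permutation p = 6.0e-05, adjusted p = 3.0e-04). Within groups 1 to 8 of HoxA, coverage was 91.0% at Hoxa1 and 14.5% at Hoxa7. The annotated models of Hoxa3, Hoxc5, Hoxd3 and Hoxd4 overlap other Hox genes, so their values are not separate from those of their neighbours.

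**Figure D3:**
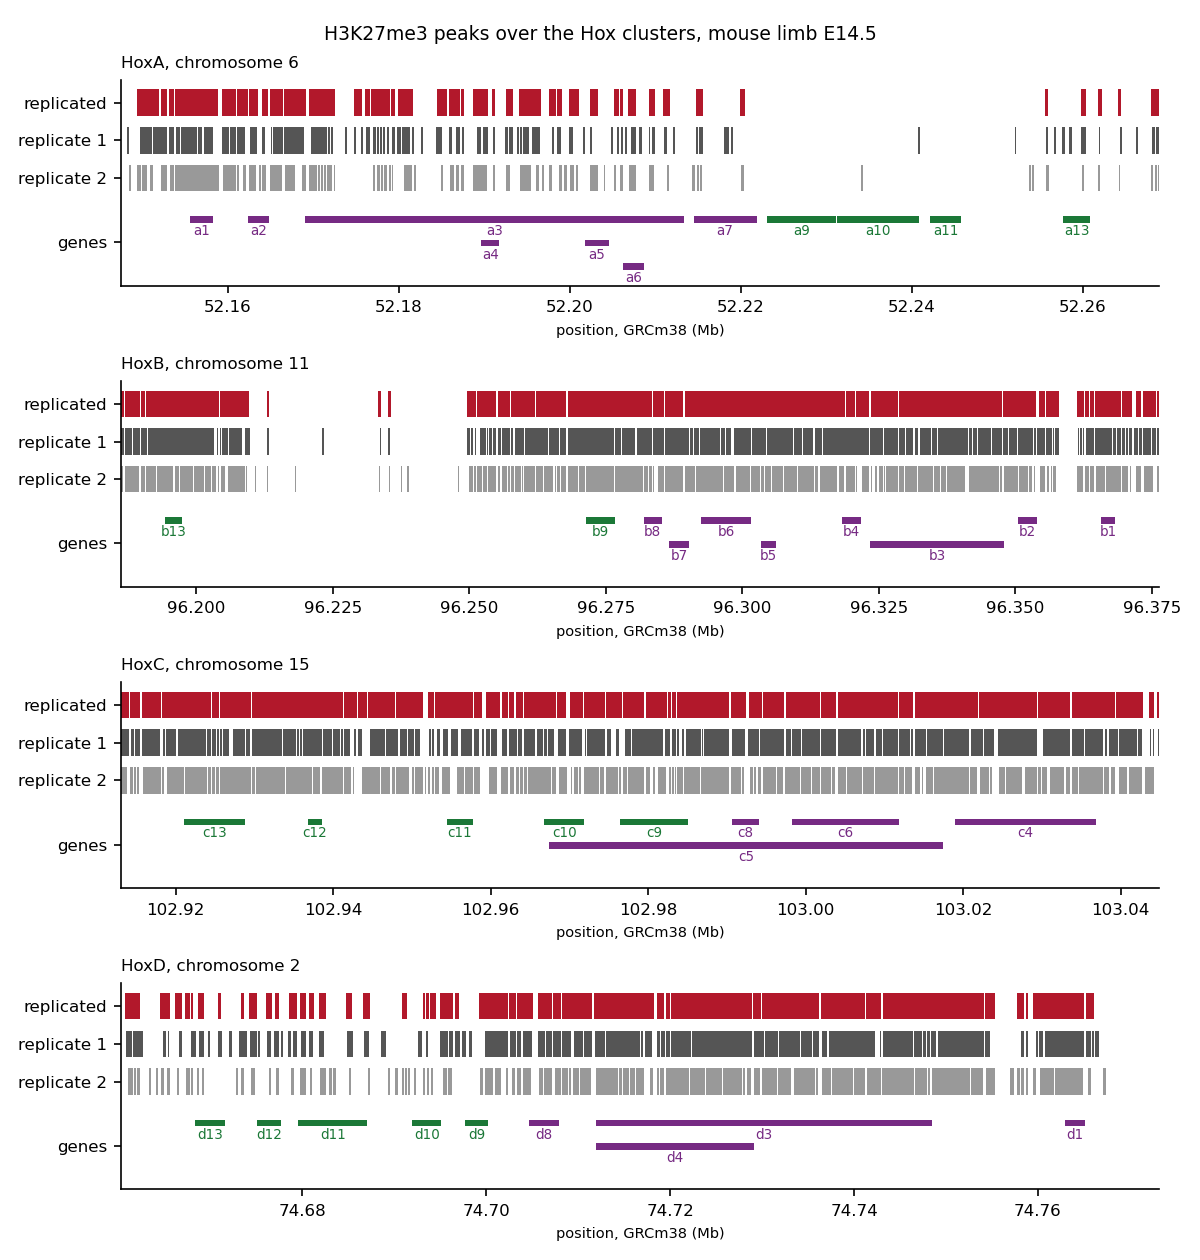
Peaks over the HoxA, HoxB, HoxC and HoxD clusters (x axis, GRCm38 position in Mb) in the replicated list and the replicate lists, with genes of paralog groups 9 to 13 in green and groups 1 to 8 in purple. HoxC is covered over 94.0% of its length, and Hoxa9, Hoxa10 and Hoxa11 carry no replicated peak.

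The rank of the X chromosome among the autosomes depended on the list and on the measure. Replicated peaks covered 2.47 kb per Mb of the X, below all 19 autosomes (3.55 to 13.2 kb per Mb, median 7.91) and 0.313 of their median. By number of replicated peaks the X lay within the autosomal range, at 4.11 per Mb against 3.47 to 10.6. In the pooled list the X reached 11.2 kb per Mb, 0.969 of the autosomal median, with 6365 peaks against 703 in the replicated list. The replicate lists lay between, at 6.02 kb per Mb (0.708 of the median) in replicate 1 and 4.10 kb per Mb (0.557) in replicate 2. Autosomes covered less than the X numbered 9 in the pooled list, 5 in replicate 1 and 1 in replicate 2. Both pools held embryos of both sexes, and 1 X chromosome against 19 autosomes gives a rank and no test.

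**Figure D4:**
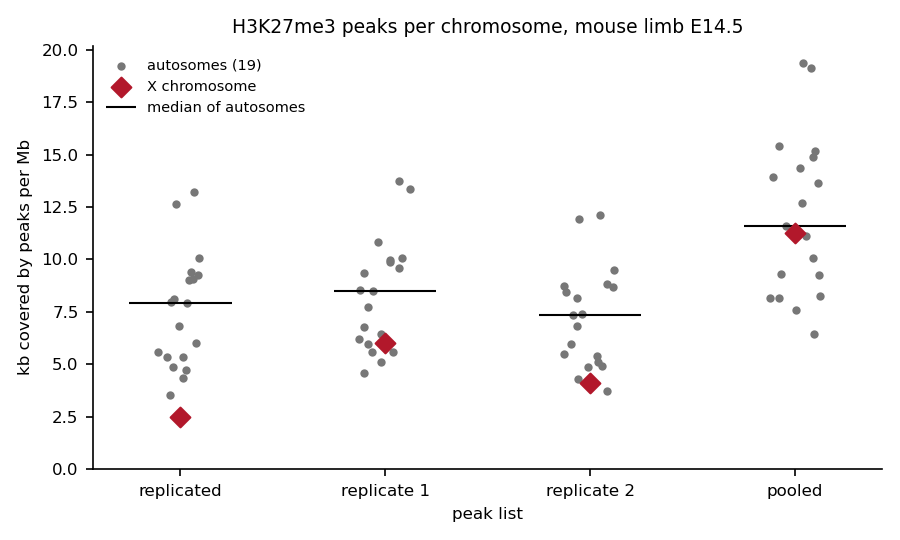
Sequence covered by peaks (y axis, kb per Mb of chromosome) for the 19 autosomes (grey), their median (line) and the X chromosome (red diamond) in each of the 4 peak lists. The X lies at 2.47 kb per Mb in the replicated list and at 11.2 kb per Mb in the pooled list.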

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

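Sequencing depth is unknown, so none of these values could be set against read numbers, and each replicate is 1 pool of embryos. The gap between limb patterning genes and neural transcription factors and that between Hox groups 9 to 13 and 1 to 8 over all clusters kept their direction and stayed past 0.05 in every setting run, and the number of gene lists past 0.05 ranged from 22 to 25. The share of peaks found in both replicates moved in each setting. It was 49.7% of replicate 1 and 58.6% of replicate 2 at −log10 q of at least 2, 56.4% and 61.6% at −log10 p of at least 5, and 57.5% and 60.9% with the same number of strongest peaks. Stricter overlap lowered it to 34.2% and 42.6% (50% of either peak) and to 18.6% and 21.9% (50% of both peaks), and merging peaks within 1 kb gave 26.2% and 32.9%. In the first 3 of these settings and after merging, the Jaccard index was 0.428, 0.458, 0.459 and 0.460. The correlation of fold in those first 3 settings was 0.432, 0.413 and 0.412 (Spearman) and 0.482, 0.457 and 0.456 (Pearson), and with 50% of both peaks it was 0.559 and 0.619. Peaks of replicate 1 alone numbered 12819 at −log10 q of at least 2 and 8434 at −log10 p of at least 5, those of replicate 2 alone 9319 and 7175, and 20614 replicate 1 and 14114 replicate 2 peaks had no peak of the other list within 1 kb. The replicated share of pooled peaks was 23.3% when rebuilt with 1 bp in each replicate list, 8.99% with 50% of both peaks, and 42.5% among pooled peaks with −log10 q of at least 2. Coverage of the X chromosome over the autosomal median was 0.969 with pooled peaks and 0.557 to 0.708 without a replicate (whole lists). Enrichment at gene starts was 7.01-fold with pooled peaks, 9.02-fold to 9.11-fold without a replicate, 9.40-fold at −log10 p of at least 5, 10.3-fold with 1 kb, 6.02-fold with 5 kb and 10.01-fold with the 5′ end only. Beyond the mean of label permutations within CpG classes, the gap in coverage between limb patterning and muscle lineage genes was −1.26 percentage points. Stricter thresholds and overlaps change the count of peaks by construction, and for the other values the cause was not tested. Of the further comparisons 115 kept their side of 0.05, 3 lost the call and 1 (the −1.26 above) lost it and turned, of the gene list results 311 kept it, 3 gained and 5 lost the call, and of the values of named genes 731 stayed within the spread of the replicates and 244 moved. No paired analysis was possible because all samples belong to 1 group.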

Other observations

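Tests of gene families by symbol, the counts by gene type, the bound from other peaks of no higher fold, the test of unusually strong enrichment, the test of diffuse enrichment on the X chromosome, and the bounds by which the planned CpG and pooled-list alternatives were read as tests of the limb gap were chosen only after the result was seen. Beyond the fixed lists, genes were grouped by symbol. Among 266 groups of protein-coding genes sharing a symbol stem, 19 were marked more often and 8 less often than other genes (Fisher's exact test, adjusted p under 0.05). A shared stem, such as Fam, need not make the genes a biological family. Synaptotagmins, the calcium sensors of vesicle release, were marked in 13 of 17 cases (exact p = 3.5e-08, adjusted p = 2.4e-06), serotonin receptors in 11 of 14 (2.7e-07, adjusted 1.4e-05) and Kcnk potassium channels in 10 of 14 (4.1e-06, adjusted 1.84e-04). Syt6 was covered at 68.6% of the 10 kb around its start (63.3 ± 1.95% in the replicate lists, SD, n = 2), Htr1a at 41.2% (35.6 ± 5.55%), Kcnk12 at 69.2% (59.8 ± 0.615%) and Kcnk9 at 62.5% (60.4 ± 0.262%). Solute carriers were marked in 99 of 370 cases (26.8%, exact p = 1.6e-08, adjusted p = 1.4e-06), phosphodiesterases in 13 of 26 (3.90e-05, adjusted 0.00130) and Rgs regulators of G protein signalling in 12 of 23 (4.52e-05, adjusted 0.00134). Non-clustered protocadherins were marked in 8 of 12 (exact p = 8.77e-05, adjusted p = 0.00194). The other stems marked more often, at adjusted exact p of 0.00194 to 0.0479, were Fam (53 of 202), Hs (8 of 12), Galnt (9 of 17), Cacna (8 of 14), Mapk (9 of 18), Kcnj (8 of 15), Pou (7 of 12), Nr (11 of 26), Col (13 of 35), Gpr (22 of 73), Scn (7 of 14) and Adamts (8 of 19). Among the stems marked less often were vomeronasal receptors (0 of 329, exact p = 1.4e-24, adjusted p = 3.9e-22), Zfp zinc finger genes (20 of 393, 5.09%, 1.9e-10, adjusted 2.6e-08) and histone genes (0 of 67, 2.32e-05, adjusted 8.82e-04). Unlike the fixed lists, the stems were not tested with CpG matching or rotation along the gene order.

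The most covered microRNA genes included several in Hox clusters, and shares by gene type were not tested against each other. Mir9-3, whose product acts in neural progenitors, was covered over 100% of the 10 kb around its start, Mir10a in HoxB over 99.2%, Mir10b in HoxD over 97.7%, Mir615 in HoxC over 96.9% and Mir196a-1 in HoxB over 96.0%. Of 2202 microRNA genes, 119 (5.40%) had a peak at the 5′ end, against 14.6% of protein-coding genes, as did 356 of 2959 antisense transcripts (12%) and 350 of 5854 long intergenic non-coding RNA genes (5.98%). Processed pseudogenes were marked in 97 of 9940 cases (0.976%). Of the genes more than 10 kb from a protein-coding start, 3.50% of microRNA, 3.44% of antisense and 3.87% of long intergenic genes had a peak.

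The smallest p-values of the replicated list included 3 peaks with fold values below its median of 3.74, at chromosome 17:39843001-39846805 and 17:39847858-39848930, on ribosomal RNA sequence, and at 11:109011578-109012088. Unusually strong enrichment could not be weighed, because the peaks were picked for a fold at or below the median, which fixes their highest fold of 3.14 below the 95th percentile of 6.62. The 3676 other peaks of no higher fold had a median −log10 p of 5.22 and a maximum of 29.1, against 49.9 for the chromosome 11 peak and 151 and 130 for the chromosome 17 pair, and though this met a bound of 50% set after the values were seen, it leaves multi-copy sequence open because the 3 peaks were picked for their p-values. A test written earlier asked for under 10% of 31-base words found elsewhere in the reference, and the chromosome 11 peak met that bound with 7.69%, but the ribosomal pair, a known multi-copy sequence, also scored only 6.20% and 7.19%, so the bound was set aside after the value was seen. A peak above the median fold, in an intron of Cdk8 (chromosome 5:146260994-146261489, fold 5.03), had a −log10 p of 90.3. Of its 31-base words 14.6% lay elsewhere, and it was outside these tests. Multi-copy sequence missing from the reference cannot be told apart from enrichment of the mark at the 3 peaks, and no biological explanation was tested.

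The X chromosome was covered by pooled peaks about as much as the autosomes and by replicated peaks less than any of them. Over the 19 autosomes, repeat-masked percent and coverage by pooled-only peaks correlated with Spearman's rho of −0.575 (permutation p = 0.0112). More repeats thus did not go with more coverage among autosomes. The X lies far outside their range, with 46.8% masked against 30.6% to 35.8%. High repeat content therefore stays open as a reason for its pooled-only peaks. Peaks called within repeat copies were argued against by unmasked sequence, where such peaks covered 14.8 kb per Mb on the X (autosomes 3.88 to 8.31), and scarce CpG-rich starts as the whole reason by the 10.8% of X genes that were marked, against 15.8% of autosomal genes and 13.5% of CpG-matched ones (permutation p = 0.0118, from random draws of genes). Diffuse weak enrichment stays open, since the 8.77 kb per Mb in pooled-only peaks (autosomes 2.89 to 6.45) restates the pattern. Both pools mixed the sexes, so an origin in the inactive X of female embryos stays open as well, and no biological explanation was tested.

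Limb patterning genes were less covered than neural transcription factors. Beyond the mean of label permutations within CpG classes, a gap of −35.4 percentage points remained. It argued against CpG content within 2 kb of the 5′ end as the whole reason. CpG content further out in the 10 kb was not matched and stays open. In the pooled list the gap was −33.5 points, against −38.4 in the replicated list. Peaks that only the pooled list holds thus did not close it. Fragments that miss the threshold of the pooled list as well stay open. The gap in the share of marked genes went from −17.8 points in the replicated list to −9.76 in the pooled list. Among genes with a peak, the highest fold was lower at limb patterning genes (5.78 ± 1.39, SD, 33 genes) than at neural factors (7.33 ± 1.39, 59 genes), a difference of −1.55 (permutation p = 2.0e-05, the smallest possible). Fold and coverage go together over marked genes (Spearman's rho 0.810), and beyond the fold of 50 other marked genes of nearest coverage the difference was −0.417 (permutation p = 0.115), in a test added after the fold difference was seen. A mark present in part of the cells therefore stays open, since the lower fold is not separate from the lower coverage. No other biological explanation was tested.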
